A study of Mus musculus with 8 samples.

How the data were processed

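The series measured single-cell gene expression in 8 mouse kidney libraries, 4 sham and 4 RAS, whose groups and numbers come from the labels. Per the labels' protocols, kidneys were dissociated and then sorted by flow cytometry. The deposited values are whole-number UMI counts per gene and cell barcode, with 27998 genes per library, and per the submitters' processing notes Cell Ranger 2.0.0 and the mm10 build were used. How barcodes were kept, whether counting used strand and which annotation release was used are not given in the sources used here. Every library had its own lowest number of UMIs per barcode, from 529 to 1815, so the deposited barcodes had already passed a filter.

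Barcodes with at least 500 UMIs and at most 50% mitochondrial UMIs were kept. The doublet caller scrublet was run on each library, and since its automatic threshold failed in 4 libraries (marking 0 barcodes in sham1, RAS2 and RAS3 and 0.023% in RAS4), the 5% of barcodes with the highest score were left out in every library. Counts were scaled to 10000 UMIs per cell and log transformed, and 2000 variable genes, 30 principal components and 15 neighbours entered Leiden clustering at a resolution of 1.0 (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15). Of 30 clusters 18 took a class name from marker lists and 12 stayed unnamed. A cluster was named where the mean of its marker scores was at least 0.6 and at least 2 times the next class's, where at least 3 markers were seen in 10% of its cells at 2 times the level elsewhere, and where its 10 leading genes held no more markers of another class than of its own. A shallow cluster, far below its libraries' median depth, with no own marker among those genes also stayed unnamed. These thresholds were not among the choices fixed in advance. The unnamed clusters held 18.2% ± 2.64 of sham and 34.3% ± 30.4 of RAS cells (SD, n = 4 each).

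Counts were summed per library over all kept cells and over the cells of each class, and a library with fewer than 20 cells of a class was left out of it. The edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling and edgeR's expression filter compared RAS with sham, with Benjamini-Hochberg adjustment and a threshold of 0.05. DESeq2 1.42.0 and limma voom (limma 3.58.1) were alternatives. Class shares were tested with edgeR on cell numbers, and with a 2-sided exact permutation test over the 70 assignments of 4 against 4 libraries, whose smallest p is 0.0286. There were 43 lists, 28 of genes and 15 of class markers, tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, where at least 5 genes of a list were measured. In the counts past the test over the lists, 17 of 33 passed in the proximal tubule-like, 17 of 26 in the thick ascending limb-like, 14 of 27 in the intercalated cell-like and 25 of 43 in the whole-library sums. With an estimated correlation 2, 0, 0 and 0 passed there, and 1 of 28 in B cell-like cells.

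Groups, tests, marker and gene lists, the naming rule and 21 alternatives were fixed before the data were examined. Genes named in the text were, in the proximal tubule-like class, up to 10 in each direction, and in each other class up to 3, by size of change among genes past the threshold with at least 20 CPM in the group with the higher level and groups that did not overlap. Outside the proximal tubule-like class such a gene also had to be higher in the class than in the whole-library sums. Where no gene passed, the 5 with the smallest p were named as not past the threshold. Genes whose symbol more than 1 identifier holds were passed over when the rule was applied, which the rule as fixed did not say, and this left out Ccl21a in the endothelial-like class. A set of genes was given whatever its result, and of each list the 2 to 4 members with the smallest p, while further called genes named in the text, such as Cdkn1a in the thick ascending limb-like class and Ddit4 in the endothelial-like class, are members of such lists. Of 64 named genes, 23 overlap another gene in the GENCODE annotation used here for coordinates and 12 overlap one on the same strand, so their counts carry that uncertainty. The same holds for genes with near-identical copies, such as Tuba1a, Lyz2 and the MHC genes.

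The tests were tested on simulated data drawn from the real means and library sizes with 200 changed genes. Of genes changed 4-fold, 89.4% were recovered in the proximal tubule-like class (10723 genes), 72.7% in the thick ascending limb-like class (6159), 75.8% in the intercalated cell-like class (5750) and 68.2% in the whole-library sums (14863). Of genes changed 2-fold, 17.9%, 9.0%, 28.4% and 6.0% were recovered. In each of these, a list of 20 genes moved 1.5-fold was called and 0 of 40 unchanged lists were. The genes were drawn independently of each other, so this does not measure false calls of lists whose genes move together. Other splits of the real libraries called up to 31 lists in the whole-library sums and 20 in the proximal tubule-like class.

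Whether the shared numbers of sham and RAS libraries pair the samples was checked from the correlation of their deviations from the group means. In the whole-library sums all 4 same-numbered pairs were over 0.1 (0.161 to 0.642) and 6 of 8 libraries correlated best with their own number, so the numbers were taken to pair the samples. Yet sham1 correlated better with RAS2 (0.499) than with RAS1 (0.161), and sham4 with RAS3 stood at 0.237. Sham1 with RAS3 stood at -0.427 and sham4 with RAS2 at -0.608. The check cannot tell pairs from a difference between libraries numbered 1 and 2 and those numbered 3 and 4. No term for that difference was fitted, so results with the replicate block rest on assumed pairs. No label says what a number marks. Within classes the lowest pair lay between -0.108 (endothelial-like) and 0.108 (B cell-like), and in the proximal tubule-like class the pairs ran from -0.013 to 0.576. Values with the replicate block therefore stand beside the results whose calls or counts they change.

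Library pairs within a group differed beyond sampling noise, with a chi-square per gene of 21.0 to 597, so no library was counted as a copy. After the data had been seen, 8 settings were added, among them a single UMI minimum of 1815, RAS3 and RAS4 left out, the library set as a term, tubule-like cells without any UMI of 12 phagocyte markers, as many cells drawn at random, and each thick ascending limb-like cluster alone. The library sets were defined from the data by a median mitochondrial share above or below 8%, with 4 libraries in each. Depth differed between classes and libraries, with sums of between 103598 and 1340779 UMIs per library in the thick ascending limb-like class (31 to 1034 cells) and between 311761 and 12739248 in the proximal tubule-like class (122 to 5555 cells). The Ighm, Trac, Trbc2 and Cebpd genes of the lists had no row under these names.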

Results

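Single-cell RNA sequencing was analysed from mouse kidneys, 4 after sham surgery and 4 after chronic ischemia from narrowing of a renal artery on one side (renal artery stenosis, RAS). Per the labels, the kidneys were taken after 4 weeks from mice aged 8 months, dissociated to single cells and sorted by flow cytometry to remove debris and dying cells. Each library is named here by its group and number (sham1 to sham4, RAS1 to RAS4). The deposited counts are molecules tagged by unique molecular identifiers (UMIs), and library totals ran from 19282922 UMIs (sham4) to 52229744 (RAS3). The libraries held 18831, 20094, 9755 and 6332 barcodes in sham1 to sham4 and 8767, 13925, 46251 and 8613 in RAS1 to RAS4, and 113214 of the 132568 barcodes were kept. Median UMIs per kept cell were 1361, 1574, 2651 and 2457 in the sham libraries and 2805, 2826, 928 and 2884 in the RAS libraries. The labels give 4 samples per group without identifying the animal behind each, so p-values measure the spread between these samples. Xist, the RNA that marks female cells, was under the count filter in the whole-library sums, and the Y-linked genes Ddx3y and Eif2s3y were detected in all 8 libraries. Eif2s3y stood at 39.3 ± 3.77 CPM (counts scaled to equal library totals) in sham and 41.3 ± 13.9 in RAS (SD, n = 4 each).

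The first comparison asked how the makeup of the kidney cell suspensions differed between sham and RAS. Thick ascending limb-like cells, named for a salt-reabsorbing segment, averaged 5.19% ± 1.19 of kept cells in sham and 1.48% ± 0.873 in RAS (SD, n = 4 each), and by this share every RAS library lay below every sham library. Cluster 6 of this class, led by the uromodulin gene Umod, held 31.7% of the class in sham and 75.1% in RAS. It held 53 of the 5261 kept cells of sham4 and 111 of the 7571 of RAS1. For the share of that cluster alone the groups therefore overlapped, and it was not tested. Endothelial-like cells averaged 19.9% ± 4.64 in sham and 5.72% ± 7.53 in RAS, and mesenchymal-like cells, the matrix-producing and contractile cells, 1.83% ± 1.49 and 6.52% ± 3.70. Proximal tubule-like cells averaged 27.7% ± 6.31 in sham and 14.0% ± 13.8 in RAS, where RAS1 and RAS2 (26.6% and 25.2%) lay within the sham range and RAS3 and RAS4 at 2.47% and 1.49%. Mononuclear phagocyte-like cells averaged 8.93% ± 2.69 and 14.6% ± 8.71, and B cell-like cells 2.67% ± 0.491 and 8.77% ± 12.8, with 27.9% of the cells of RAS4 and at most 4.08% of those of any other RAS library.

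No class passed the test of shares. The edgeR log2 ratios of RAS to sham were -1.81 ± 0.824 (SE) for thick ascending limb-like, -1.80 ± 0.844 for endothelial-like, 1.82 for mesenchymal-like and 1.72 ± 0.834 for B cell-like cells, each at adjusted p = 0.120, and -0.99 ± 0.816 for proximal tubule-like cells (adjusted p = 0.327). The 2-sided exact permutation test gave p = 0.0286 for the thick ascending limb-like share, the smallest p that 4 against 4 libraries allow, and 0.126 after adjustment over the classes. It gave 0.0571 for endothelial-like, mesenchymal-like, distal convoluted tubule-like and intercalated cell-like shares. Without RAS4 the B cell-like ratio was -0.17, with RAS3 and RAS4 both left out -0.01 and with the replicate block 0.52, so RAS4 alone carried it. The block moved the endothelial-like ratio to -3.33 (adjusted p = 0.0548) and the proximal tubule-like ratio to -1.92, and neither passed. Cells in unnamed clusters made up 78.9% of RAS3 and between 13.1% and 27.3% of each other library. Unnamed cluster 13 scored highest for endothelial markers, at 0.552 under the 0.6 needed. It held 18.2% of RAS3 and at most 0.472% of each other RAS library. Cluster 9 scored highest for mononuclear phagocyte (0.532) and cluster 8 for proximal tubule markers (0.393), with 18.5% and 7.42% of RAS3. The RAS3 shares of these classes therefore depend on the naming threshold. As a share of named cells the thick ascending limb-like ratio was -0.70 (adjusted p = 0.508), and RAS3 then lay above every sham library. With RAS3 and RAS4 both left out, the thick ascending limb-like (-1.74), mesenchymal-like (2.01), mononuclear phagocyte-like (1.21) and neutrophil-like (1.54) ratios passed, the first at adjusted p = 0.0177, while the endothelial-like ratio was -0.86. Without RAS1, the endothelial-like ratio was -3.21 and passed at adjusted p = 0.0247. The suspensions had been sorted. The lowest UMI count per barcode ran from 529 (RAS3) to 1815 (RAS4), so these are shares of sorted cells above different depth limits. With the same UMI minimum in every library the mesenchymal-like ratio was 0.95 (adjusted p = 0.409).

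**Figure D1:**
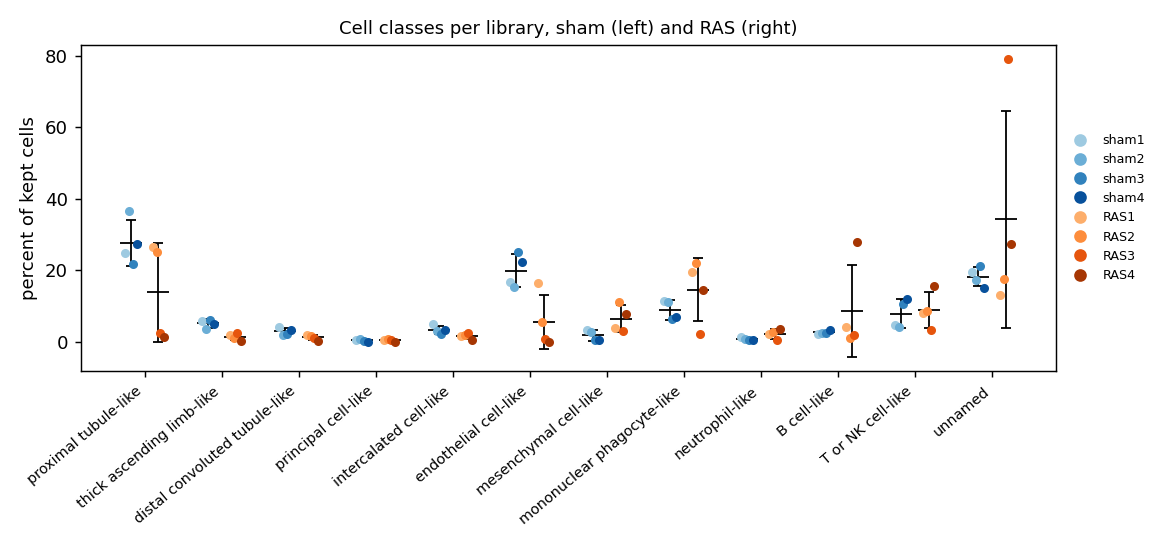
Percent of kept cells in each cell class (vertical axis) for the 8 libraries, sham in blue at the left and RAS in orange at the right of each class, with the group mean and its SD as a bar and whiskers (n = 4). The thick ascending limb-like points of RAS, 0.379 to 2.43%, lie below those of sham, 3.52 to 6.15%, and RAS3 holds 78.9% of its cells in unnamed clusters.

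The next comparison asked which genes differed in the proximal tubule-like class, the segment that reabsorbs most of the filtrate and takes the main injury in ischemia. As groups, secreted factors and complement stood higher in RAS. The list of secreted factors of senescent cells rose (19 genes measured, median log2 ratio 1.63, 13 of them higher when adjusted over the list alone), led by the chemokines Ccl8 (0.571 ± 0.0871 CPM in sham, 9.63 ± 7.21 in RAS), Cxcl2 (4.97 ± 2.46 and 23.9 ± 6.65), Ccl7 (1.05 ± 0.619 and 9.54 ± 4.30) and Cxcl1 (0.661 ± 0.477 and 10.1 ± 6.67; SD, n = 4 each). Averaged over the whole libraries, Ccl8 stood higher, at 46.5 CPM, and so did Cxcl1, at 97.8. These low levels therefore do not show that proximal tubule-like cells themselves made the chemokines. The complement list rose by a median of 1.22 (8 of 11 genes higher when adjusted over the list alone), with C3 at 1.55, C1qc at 1.69 and C1qb at 1.76. These 2 lists passed both with the preset correlation and at adjusted p = 0.021 with an estimated correlation. With an estimated correlation no list passed without sham2, without RAS2, without RAS3 or without both RAS3 and RAS4, nor with the library set as a term, each cell's own score, equal cell numbers or the replicate block. The macrophage-made C1q chains and the markers of mononuclear phagocytes moved with them: 11 of the 11 measured phagocyte markers were higher in RAS, 6 of them when adjusted over the list alone, with a median of 1.53 and Lyz2 at 2.47 (adjusted p = 0.103 with an estimated correlation).

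Other lists passed with the preset correlation only. The NF-kB and cytokine response list, whose genes answer inflammatory signals, had a median of 1.48 (15 of 21 genes higher when adjusted over the list alone; adjusted p = 0.0675 with an estimated correlation) and tubule injury and failed repair 0.93 (8 of 19; 0.0675). The dissociation response, immediate early and heat shock genes that answer tissue handling, had a median of 0.95 (9 of 24, among them Junb, Zfp36, Egr1 and Hspa1b; adjusted p = 0.123 with an estimated correlation) and presentation by MHC class II 1.78 (7 of 7, among them Cd74 and H2-Aa; 0.103). Mature transport and metabolism genes of the segment did not pass, with a median of 0.01 over 30 genes (camera adjusted p = 0.195). Neither did Slc34a1, the apical phosphate transporter (0.08 ± 0.207 SE), Lrp2, the endocytic receptor megalin (0.04 ± 0.261), and Cyp2e1 (-0.01 ± 0.173). The tricarboxylic acid cycle list stood lower by a median of -0.23 and nuclear oxidative phosphorylation by -0.17 (adjusted p = 0.486 and 0.725 with an estimated correlation).

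Gene by gene, 0 of 10723 genes passed edgeR's quasi-likelihood test in this class, with 436 at an unadjusted p under 0.05, fewer than the 5% that chance gives. DESeq2 called 70 genes and limma voom 0. With the replicate number as a block edgeR called 99 genes, 95 higher and 4 lower, while neither of the 2 lists kept its call with an estimated correlation. The lowest adjusted p values belonged to Ccl8 (0.0513), then Ccl9, Cxcl2, Ccl7 and Cxcl1 (0.191 each), and all 5 passed with the block. Among genes named in advance, Vim, an intermediate filament of injured tubule cells, stood at 2.04 ± 0.499 (SE; adjusted p = 0.305; with the block 2.21, past the threshold), Spp1, the secreted osteopontin, at 1.11 ± 0.326 (0.558; with the block 1.12, past the threshold). Vcam1 stood at 1.53 ± 0.468 (0.628), Cdkn1a, a cell cycle inhibitor, at 0.96 ± 0.395 and Krt18 at 0.86 ± 0.408 (0.999 each). Within the libraries of high and low mitochondrial share Vim stood at 2.93 and 0.84, Spp1 at 0.42 and 1.81, Vcam1 at 2.36 and 0.42 and Cdkn1a at 1.38 and -0.03. The injury genes Havcr1 and Lcn2 and the senescence gene Cdkn2a were under the count filter. Groups did not overlap for 2.86% of genes, the 2.86% that chance gives with 4 against 4. With RAS3 and RAS4 both left out 0 genes passed. In the libraries with a high mitochondrial share (sham1, sham2, RAS2 and RAS3) edgeR called 15 genes, in the others (sham3, sham4, RAS1 and RAS4) 0.

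In the thick ascending limb-like class, 225 genes rose and 52 fell among 6159 tested (edgeR's quasi-likelihood test, adjusted p under 0.05). The largest rise under the fixed naming rule was in Clu, the secreted chaperone clusterin, from 26.1 ± 14.6 to 449 ± 394 CPM (4.07 ± 0.675 on the log2 scale, SE, adjusted p = 0.0110). Lcn2, the injury marker lipocalin 2, went from 7.55 ± 9.85 to 106.2 ± 94.2 (3.78 ± 0.790, adjusted p = 0.0209), and Hbegf, a growth factor that binds the EGF receptor, from 19.1 ± 11.8 to 300.2 ± 381 (3.73 ± 0.748, 0.0175; SD, n = 4 each). Of the 24 dissociation response genes 20 rose, with a median of 2.09, and 24 when adjusted over the list alone, among them the early response genes Nr4a1 (3.16), Egr1 (2.60) and Btg2 (2.47). Il2, the gene of a T cell growth factor, fell by 3.30 on the log2 scale, Hsbp1l1 fell by 2.02 and Klhdc8a fell by 1.52 (with the block by 1.44, not past the threshold). The protein-coding genes Clu (ENSMUSG00000022037), Lcn2 (ENSMUSG00000026822) and Hbegf (ENSMUSG00000024486) lie on mm10 chromosomes 14 (65968483 to 65981547), 2 (32384633 to 32388252) and 18 (36504927 to 36515805). Il2 (ENSMUSG00000027720; chromosome 3, 37120523 to 37125959) overlaps Adad1 on the opposite strand.

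Groups of genes moved as follows in this class. Of 12 NF-kB and cytokine genes 8 rose (11 when adjusted over the list alone), among them Junb (2.81), Cxcl2 (3.49) and Nfkbia (2.36). Of 10 injury genes 5 rose (8 over the list alone), among them Spp1 (2.79), and Cdkn1a rose by 2.59. Of 40 nuclear genes of oxidative phosphorylation 5 fell (23 when adjusted over the list alone), with a median of -0.57, Ndufb10 at -0.87 and Sdhc at -1.15. Of 18 genes of the tricarboxylic acid cycle 4 fell (10 over the list alone), with Idh2 at -0.99. The 13 mitochondrially encoded genes had a median of 0.20 and did not pass (camera adjusted p = 0.322). The 7 measured MHC class II genes rose, with a median of 2.63 and H2-Aa at 2.72, and so did 7 of 10 markers of mononuclear phagocytes (10 over the list alone), with a median of 2.50 and Lyz2, the macrophage lysozyme, at 3.81. All of these lists passed with the preset correlation, and none with an estimated correlation: adjusted p = 0.209 with an estimated correlation for the dissociation, injury, NF-kB, MHC class II and phagocyte lists, and 0.237 for oxidative phosphorylation and the tricarboxylic acid cycle.

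A phagocyte marker UMI was seen in 12.9 to 35.4% of the thick ascending limb-like cells of each sham library and 55.6 to 64.8% of those of each RAS library, at median depths of 1193 to 2440 and 846 to 2691 UMIs. In T or NK cell-like cells, a class not known for most of these genes, the shares were 32.5 to 58.2% and 56.3 to 80.6%. The class joined cluster 4 (led by Ppp1r1a, Wfdc15b and Nccrp1) and cluster 6 (led by Umod, Slc12a1 and Egf), and cluster 6 held 31.7% of it in sham and 75.1% in RAS. The median mitochondrial share was 7.29% in cluster 4 and 26.1% in cluster 6. Rises and falls given for the class can therefore mix expression with a shift between these clusters. Within cluster 4 alone 14 genes passed, all among the 277, and within cluster 6 alone 0 of 4039 (440 at an unadjusted p under 0.05). Among cells without a phagocyte marker UMI edgeR called 0 genes in 7 libraries (725 at an unadjusted p under 0.05), against 45 in as many cells drawn at random. The count was 17 with RAS3 and RAS4 both left out, 126 with the replicate block (117 of them among the 277), and 278 and 1104 within the libraries of high and low mitochondrial share. It was 0 when each cell was assigned from its own marker score (1412 at an unadjusted p under 0.05) and 0 with the same UMI minimum in every library (670). Leaving out a single library gave 716 (sham2), 75 (sham3), 141 (sham4), 423 (RAS1), 91 (RAS2), 107 (RAS3) and 118 (RAS4). Groups did not overlap for 17.6% of genes, against 2.86% by chance.

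**Figure D2:**
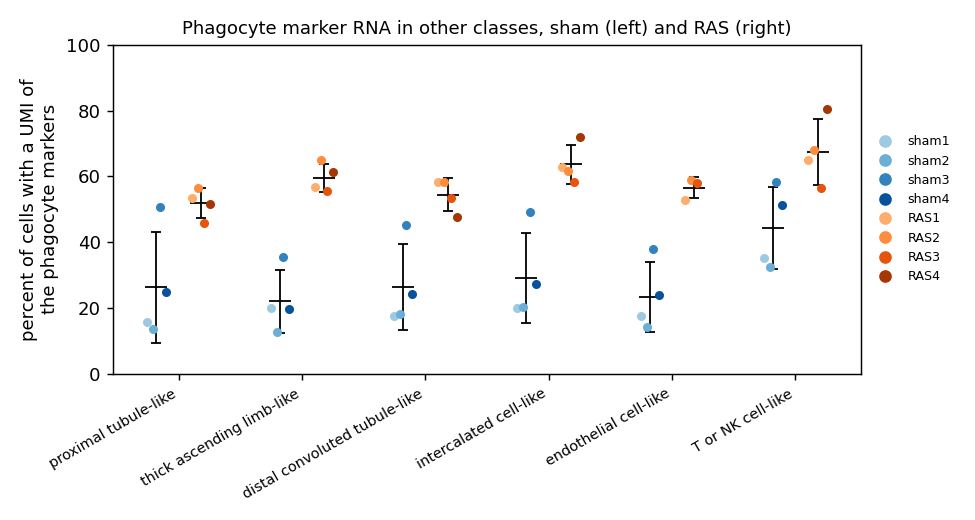
Percent of cells with at least 1 UMI of the phagocyte markers (vertical axis) in 6 cell classes, by library, sham in blue at the left and RAS in orange at the right, with the group mean and its SD as a bar and whiskers (n = 4, or n = 3 RAS libraries for the endothelial-like class). In the proximal tubule-like class the shares were 13.8 to 50.6% in sham and 46.0 to 56.6% in RAS.

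In the intercalated cell-like class, the acid and base handling cells of the collecting system, 109 genes rose and 19 fell among 5750 tested. Kit, a receptor tyrosine kinase, rose from 12.3 ± 4.13 to 55.8 ± 34.8 CPM (2.16 ± 0.438 on the log2 scale, SE, edgeR adjusted p = 0.0241). Mthfd2, a mitochondrial folate enzyme, rose from 5.90 ± 4.00 to 30.9 ± 15.6 (1.99 ± 0.458, 0.0429), and Mt2, a metal-binding metallothionein, from 144 ± 65.7 to 438 ± 144 (1.58 ± 0.300, 0.0199; SD, n = 4 each). Fabp3, a fatty acid carrier, fell from 298 ± 49.0 to 86.0 ± 33.3 CPM (-1.70 ± 0.251, 0.0144), Tg, the thyroglobulin gene, fell by 1.67 and Morn1 fell by 1.42 on the log2 scale. Of the 24 dissociation response genes 10 rose (24 when adjusted over the list alone; median 1.64), among them Junb (2.18), Egr1 (2.07) and Klf6 (2.10). Of 11 NF-kB and cytokine genes 7 rose (10 over the list alone), and both lists had adjusted p = 0.0581 with an estimated correlation. Of 18 genes of the tricarboxylic acid cycle 1, Idh2 (-0.87), fell, and 13 when adjusted over the list alone, with a median of -0.57 (adjusted p = 0.0705 with an estimated correlation).

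The 7 measured MHC class II genes rose here too (median 1.88), together with 6 of 9 phagocyte markers (9 over the list alone; median 1.86), both with adjusted p = 0.109 with an estimated correlation. A phagocyte marker UMI was seen in 20.1 to 49.2% of these cells in the sham libraries and 58.2 to 71.9% in the RAS libraries. The count of 128 genes was 0 without sham1 (900 at an unadjusted p under 0.05), 5 without sham3, 2 without sham4 and 66 without RAS3, and was 57 with RAS3 and RAS4 both left out and 92 with the replicate block (76 of them among the 128). Within the libraries of high and low mitochondrial share, 2 against 2, it was 0 and 1. Among cells without a phagocyte marker UMI edgeR called 6 genes in 7 libraries, and 2 in as many random cells. Each of the 6 named genes missed the threshold without sham1 and without sham4, and with the replicate block so did Mthfd2, Tg and Morn1. Tg and Fabp3 overlap genes on the opposite strand (Sla and Zcchc17).

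In the endothelial-like class, from which RAS4 was left out with 11 cells, 16 genes rose and 1 fell among 10825 tested. The fall, the largest change, was in Ccl21a (ENSMUSG00000094686), a chemokine of lymphatic vessels, from 35.4 ± 24.4 to 0.449 ± 0.393 CPM (-5.79 ± 0.912, SE, edgeR adjusted p = 0.0288). Its symbol is held by 2 identifiers in the counts, of near-identical genes, so its counts are uncertain, and it was named only after its values were seen. Lrg1, a secreted glycoprotein of vessel growth, rose from 10.8 ± 4.95 to 133 ± 144 CPM (3.67 ± 0.594, SE, edgeR adjusted p = 0.0326). Inhbb, a subunit of activin, rose from 9.43 ± 1.98 to 49.1 ± 29.0 (2.55 ± 0.336, 0.0141), and Fkbp5, a glucocorticoid-responsive chaperone, from 12.5 ± 2.99 to 37.2 ± 4.43 (1.61 ± 0.240, 0.0210; SD, n = 4 sham and 3 RAS). Of 22 NF-kB and cytokine genes 4 rose, Tnfaip3 (1.78), Nfkbiz (1.48), Cxcl1 (3.64) and Ccl2 (2.61), and 17 when adjusted over the list alone (median 1.42; adjusted p = 0.109 with an estimated correlation). The 4 stood at 34.7, 84.0, 57.7 and 23.7 CPM in RAS, below their averages over the whole libraries (84.9, 121.5, 97.8 and 135.8). These levels therefore do not show that endothelial-like cells themselves made these transcripts. The hypoxia response list as a whole did not pass (median -0.04 over 24 genes, camera adjusted p = 0.394), although its member Ddit4 rose by 1.58. Of 11 phagocyte markers 3 rose beside these genes, Lyz2 (2.36), C1qa (1.61) and C1qb (1.83), and 10 over the list alone (median 1.38). Leaving out RAS2 left 0 genes (388 at an unadjusted p under 0.05), leaving out sham1 10 and leaving out RAS3 29. Within the libraries of high and low mitochondrial share the counts were 56 and 19, the latter with 1 RAS library. Without RAS2 all 3 named genes missed the threshold, Lrg1 at 2.20, Inhbb at 2.48 and Fkbp5 at 1.53 on the log2 scale, and Lrg1 also missed it by limma voom.

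**Figure D3:**
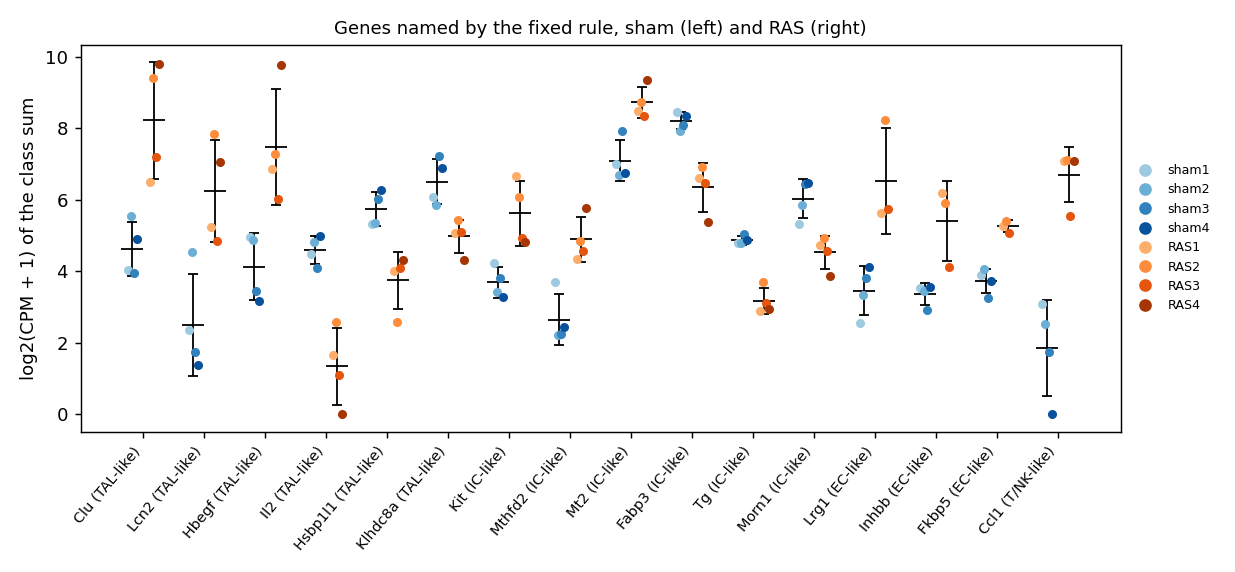
Level of each gene past the test under the fixed naming rule, as log2 of CPM plus 1 in the class sum (vertical axis), by library, sham in blue at the left and RAS in orange at the right, with the group mean and its SD as a bar and whiskers (n = 4, or n = 3 RAS libraries for the endothelial-like class, EC-like). TAL-like is the thick ascending limb-like and IC-like the intercalated cell-like class. No RAS point overlaps the sham points of its gene, from Ccl1 at 5.20 to Il2 at -3.30 on the fitted log2 scale. Ccl21a is not shown.

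Among immune classes, Ccl1, a chemokine of activated T cells, rose in T or NK cell-like cells from 3.63 ± 3.20 to 112 ± 44.8 CPM (5.20 ± 0.589, SE, edgeR adjusted p = 0.0197; SD, n = 4 each), the only gene of 8640 past the test there. It missed the threshold without sham1, sham2, sham3 or RAS2, leaving 0 genes each time, and 9 genes passed without RAS1 and 3 without RAS3. With RAS3 and RAS4 both left out 2 genes passed, and with the replicate block 53. Within the libraries of high and low mitochondrial share the counts were 3 and 0. In the same class the interferon response list had a median of 0.43 over 24 genes, of which 23 were higher in RAS and 0 passed when adjusted over the list alone (adjusted p = 0.449 with an estimated correlation). Proliferation had a median of 0.59 (3 of 11 genes over the list alone, adjusted p = 0.449 with an estimated correlation). The 8 measured phagocyte markers had there a median of 1.94, with 7 higher and 1 lower over the list alone.

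In mononuclear phagocyte-like cells 0 of 9750 genes passed edgeR's test, with 809 at an unadjusted p under 0.05, 56 genes by DESeq2, 1 by limma voom and 5 with the replicate block. The smallest p belonged to Mmp13, a collagenase, at 258 ± 11.5 CPM in sham and 98.5 ± 18.3 in RAS (-1.38 ± 0.172, SE, adjusted p = 0.0861, with the block 0.0428), and then to Adam8 (3.09), Abca1 (1.86), Fosl2 (2.72) and Nccrp1 (-2.05). By their medians, proliferation genes stood higher in RAS (0.59 over 13 genes, 3 over the list alone, with Top2a at 1.28 and Mki67 at 1.88), and so did secreted factors of senescent cells (1.10 over 26 genes, 14 higher and 1 lower over the list alone). Neither held with an estimated correlation (adjusted p = 0.424 and 0.495 with an estimated correlation). MHC class II genes had a median of -0.04 over 8 genes in this class (camera adjusted p = 0.625). Cluster 10, led by Retnla, Cxcl2 and Cd14, held 27.1% of the class in sham and 43.8% in RAS, and cluster 20, led by C1qa, the rest. Without RAS3 20 genes passed, without RAS4 1, and with both left out 31.

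In the remaining classes edgeR called 0 genes. Within the libraries of high and low mitochondrial share it called 11 and 1 in the distal convoluted tubule-like, 0 and 125 in the mesenchymal-like, 1 and 0 in the neutrophil-like and 32 and 0 in the B cell-like class. Distal convoluted tubule-like cells had 739 of 5447 genes at an unadjusted p under 0.05, 51 genes by DESeq2, 0 by limma voom and 2 with the block, and Apoe (2.59 ± 0.397, SE; with the block 2.55, past the threshold), Tuba1a (2.15), Lyz2 (2.38), H2-Aa (1.89) and Larp1b (-1.07) had the smallest p (adjusted p from 0.0558 to 0.0746). Of its 24 dissociation response genes 16 were higher when adjusted over the list alone (median 1.22), beside 7 of 7 MHC class II genes and 6 of 6 phagocyte markers (adjusted p = 0.203 with an estimated correlation for each). The count of genes was 83 without RAS1, 6 without RAS3, 1 without RAS4 and 1 without sham3, and 7 with RAS3 and RAS4 both left out. Mesenchymal-like cells had 424 of 9543 genes at an unadjusted p under 0.05, 33 by DESeq2, 0 by limma voom and 7 with the block, led by the phagocyte genes Cd14 (1.75), Lyz2 (3.19; with the block 2.91, past the threshold), Il1b (3.20) and Ctss (2.60) and by Igfbp3 (-2.55; past the threshold with the block). In this class 7 of 9 phagocyte markers were higher over the list alone (median 2.56). Its cluster 27, led by Dcn, held 49.3% of the class in sham and 75.2% in RAS. Neutrophil-like cells had 194 of 3544, 4 by DESeq2, 0 by limma voom and 0 with the block, and B cell-like cells 305 of 5842, 13 by DESeq2, 0 by limma voom and 1 with the block. In B cell-like cells Mgl2 (2.13), Aif1 (1.67), Cxcl2 (2.69; with the block 2.75, past the threshold), Ms4a6c (1.49) and Klf2 (-1.33) had the smallest p, each at adjusted p = 0.477. In neutrophil-like cells Ms4a4b (3.05), Tmem213 (-2.18), Pecam1 (-1.42), Trem2 (1.41) and Ccl5 (4.73) had the smallest p, each at adjusted p = 0.494.

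In the whole-library sums, where makeup and expression are mixed, 0 of 14863 genes passed edgeR's test, with 3588 at an unadjusted p under 0.05, 1695 genes by DESeq2, 0 by limma voom and 0 with the block. Groups did not overlap for 20.7% of genes, against 2.86% by chance. The genes with the smallest p, at adjusted p = 0.0697 each, were the phagocyte and dendritic cell genes Trem2 (6.65 ± 1.25 CPM in sham and 26.5 ± 5.75 in RAS, SD, n = 4 each), Csf2rb (2.03 ± 0.253 on the log2 scale, SE), Batf3 (1.30 ± 0.170) and Itgax (1.29 ± 0.170), and Camk1d (1.26 ± 0.165), each higher in 4 of 4 RAS libraries than in any sham library. As groups, nuclear oxidative phosphorylation fell (median -0.69, 31 of 40 genes lower when adjusted over the list alone), as did the tricarboxylic acid cycle (-0.78, 16 of 18). Lists of proliferation (1.08, 17 of 24), MHC class II (1.21, 8 of 8) and NF-kB and cytokine genes (1.56, 17 of 23) rose. Markers of the proximal tubule (median -0.78), thick ascending limb (-0.99) and endothelium (-1.21) fell and those of mononuclear phagocytes rose (0.91). None of these held with an estimated correlation (adjusted p = 0.644 to 0.671 with an estimated correlation).

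Genes named in advance for the whole kidney did not pass in these sums. Cdkn1a stood at 74.7 ± 12.7 CPM in sham and 198 ± 70.3 in RAS (1.40 ± 0.272, SE, edgeR adjusted p = 0.0728), above sham in 4 of 4 RAS libraries. Col1a1, the chain of fibrillar collagen, stood at 14.3 ± 11.5 and 87.9 ± 76.4 (2.61 ± 0.872, 0.138), Lcn2 at 2.29 ± 1.46 and 10.3 ± 6.65 (2.15 ± 0.699, 0.134), and Cdkn2a at 0.618 ± 0.296 and 2.34 ± 1.60 (1.94 ± 0.610, 0.128). C3 (1.73, adjusted p = 0.263), Havcr1 (1.05, 0.351), Spp1 (0.71, 0.420) and Ren1, the renin gene (2.25, 0.448), had larger adjusted p. The Ren1 ratio rested on RAS1 and was negative without it, with the block and within the libraries of high mitochondrial share (-0.31). Within the libraries of high and low mitochondrial share Havcr1 stood at 2.95 and 0.34 and C3 at 1.12 and 3.86. Without RAS3 41 genes passed, without RAS4 209, and with both left out 10.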

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

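The tests in cells without a phagocyte marker UMI, the ratio of shares of cells with such a UMI, the count of classes for handling stress and all counts of other splits were chosen only after the result was seen.

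Of 165 groups of 4 libraries checked for a library far from the other 3 of its group, 13 were marked, where chance marks about 1 in 20 groups. RAS3 held 46251 barcodes against 8613 to 13925 in the other RAS libraries, and its median of 928 UMIs per kept cell lay below their 2805 to 2884. B cell-like cells made up 27.92% of RAS4 against 1.22 to 4.08% of the other RAS libraries. In the whole-library sums Ren1, made by cells at the vessel pole of the glomerulus, stood at 268.1 CPM in RAS1 against 0.169 to 7.90 in the other RAS libraries.

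Further single libraries stood apart for named genes. In the proximal tubule-like class these were RAS4 for Ccl8 (20.43 CPM against 5.54 to 6.42) and sham3 for Slc34a1 (2416 against 3358 to 3468). In the thick ascending limb-like class they were sham2 for Lcn2 (22.25 against 1.60 to 4.07) and RAS4 for Hbegf (868.2 against 63.2 to 154.7). Sham2 stood apart for Tuba1a in the distal convoluted tubule-like class (17.79 against 6.31 to 8.26), and sham1 for Mthfd2 in the intercalated cell-like class (11.88 against 3.59 to 4.37). In mononuclear phagocyte-like cells sham1 stood apart for Mmp13 (274.8 against 250.1 to 253.8) and sham3 for Nccrp1 (17.23 against 8.57 to 10.01), and in T or NK cell-like cells RAS3 for Ccl1 (45.3 against 133.4 to 136.3).

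Phagocyte and MHC class II transcripts were higher in RAS in the thick ascending limb-like and intercalated cell-like classes. Free RNA spread alike over all droplets is argued against as the whole source of the phagocyte transcripts in the RAS libraries. There, phagocyte marker UMIs per cell were a median of 5.03 and 4.17 times those of the proximal tubule-like class. In the sham libraries they were 0.58 to 4.0 and 0.94 to 5.9 times, so such an excess stood there too. The comparison of classes therefore does not test the rise from sham to RAS. These ratios do not cover the MHC class II transcripts. Phagocyte material confined to droplets with a marker UMI is argued against as the whole cause of the MHC class II rise in the intercalated cell-like class. Cells without a phagocyte marker UMI kept 0.94 there of the median log2 of as many random cells. In the thick ascending limb-like class they kept 0.77 (1.74 against 2.27), which leaves such material open. Cells without a marker UMI can still hold MHC class II RNA of other cells, on which this check cannot decide. In RAS1 to RAS4 such intercalated cell-like cells held 2.702, 2.696, 2.876 and 3.188 MHC class II UMIs per cell. Such T or NK cell-like cells held 2.363, 2.295, 3.567 and 6.567. Free RNA may still give part of the phagocyte transcripts, as shares of cells with a marker UMI differed up to 1.51 times between tubule-like classes of a RAS library (RAS4, with 21 distal convoluted tubule-like cells). It stays open for the MHC class II transcripts, whose UMIs per cell without marker UMIs were 0.9 of the proximal tubule-like level. A difference between sham and RAS tubule cells stays open and untested.

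Dissociation response genes were higher in RAS in the tubule-like classes. Handling stress that raises these genes in all cells alike is argued against, since the medians of mononuclear phagocyte-like (-0.08), neutrophil-like (-0.30), B cell-like (-0.28) and T or NK cell-like (-0.37) cells lay below 0. Of the 6 other tested classes 2, endothelial-like (0.53) and mesenchymal-like (0.89), had a median over 0.5. The count of classes cannot decide on a shared stress that immune classes answer less, which stays open. Phagocyte material in the droplets with a marker UMI is argued against as the whole cause, since thick ascending limb-like cells without a marker UMI gave 1.04 times the median log2 of random cells (1.51 and 1.46). The prediction also asked that the list stay past its threshold, which this check left out. Free RNA from other cells, which droplets without a marker UMI can hold too, was not tested for these genes. A shift between the clusters of that class stays open: cluster 6 alone gave 0.63 of the class value. Handling stress taken more by the classes outside the immune ones, and a response to ischemia, may both give this pattern and were not tested.

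No gene passed in the proximal tubule-like class by edgeR, with 436 at an unadjusted p under 0.05 (fewer than the 5% that chance gives, and 12 of the 35 splits held as many), 70 by DESeq2 and 0 by limma voom. A difference between the libraries of high and low mitochondrial share might hide a group difference. With the library set as a term 1 gene, Ccl8, passed, fewer than predicted for such a cause. Within the sets of high and low share alone 15 and 0 did. Without the term, the test recovered 17.9% of simulated genes changed 2-fold in this class. A single term also cannot take in changes that differ between the sets, so the few calls cannot decide. The split of the libraries by that set called 1160 genes, which points to a structure of the samples that follows neither group nor number. Whether the sets come from handling, sequencing or the animals is not given in the sources used here, and since 99 genes passed with the replicate block, a group difference hidden by differences between the pairs stays open.

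Over the 35 splits of the libraries into groups of the real sizes (4 against 4, and 4 against 3 for the endothelial-like class), no other split called as many genes as the real one in the thick ascending limb-like class (277, highest other 0, 1 split as large) and the intercalated cell-like class (128, highest other 0, 1 split). The real split always counts, so 1 of 35 is the smallest share possible. That share was read over all classes without adjustment, so chance was not excluded. Among the 8 splits that part all 4 same-numbered pairs, the highest other count was also 0 in both, but 8 splits are too few for a share under 5%. Where the real count was 0 every split is as large, so these comparisons decide nothing. The real count and the highest other were there 0 and 5 in the whole-library sums, 0 and 1160 in the proximal tubule-like, 0 and 1 in the distal convoluted tubule-like, 0 and 13 in the mesenchymal-like, 0 and 0 in the mononuclear phagocyte-like, 0 and 1 in the neutrophil-like and 0 and 3 in the B cell-like class, each with 35 splits as large. At an unadjusted p under 0.05 the whole-library sums held 3588 genes, which no other split reached (highest other 2573). Other splits called as many genes in the other 2 classes, where the counts were 17 and 242 in the endothelial-like class (4 splits as large) and 1 and 9 in the T or NK cell-like class (2 splits), so chance could not be excluded there either.

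For none of the counts of lists could chance be excluded. Splits as large, with the real count and the highest other, were 10 in the whole-library sums (25 and 31), 8 in the proximal tubule-like (17 and 20), 3 in the thick ascending limb-like (17 and 17), 2 in the distal convoluted tubule-like (17 and 19), 7 in the intercalated cell-like (14 and 19) and 7 in the endothelial-like class (17 and 22). They were 10 in the mesenchymal-like (11 and 23), 14 in the mononuclear phagocyte-like (13 and 23), 8 in the neutrophil-like (13 and 17), 13 in the B cell-like (13 and 18) and 17 in the T or NK cell-like class (11 and 20).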

How the results depend on the processing

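The settings with a single UMI minimum, RAS3 and RAS4 both left out, the share of named cells, the library set as a term, cells without a phagocyte marker UMI, random cells and single clusters were chosen only after the results were seen.

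Under the planned settings, single genes and lists stayed on the same side of the threshold, or counts of lists within 1.5 times, in 3184 comparisons. They passed newly in 189, lost the call in 121 and moved in 12. Under the added settings these were 742, 39, 68 and 5, with 12 reversed. A change of sign where neither setting passed was counted as staying on the same side, so these counts do not show that directions held. Main results, which include the shares and the gene counts per class, were counted apart and moved more often. Under the planned settings 319 of their comparisons were counted as unchanged, 71 moved and 1 passed newly. Under the added settings these were 68, 23 and 4. The cause was not tested for any change given here, except that settings with fewer libraries, cells or genes have less to test. With doublets kept no distal convoluted tubule-like or principal cell-like class was found, and at a cluster resolution of 0.5 no thick ascending limb-like, distal convoluted tubule-like or principal cell-like share. What could be found was limited: of simulated genes changed 2-fold, the test recovered 28.4% in the intercalated cell-like, 17.9% in the proximal tubule-like and 4.5% in the mesenchymal-like class.

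By DESeq2 the genes called were 1695 in the whole-library sums, 70 in the proximal tubule-like, 457 in the thick ascending limb-like, 51 in the distal convoluted tubule-like, 221 in the intercalated cell-like, 71 in the endothelial-like, 33 in the mesenchymal-like, 56 in the mononuclear phagocyte-like, 4 in the neutrophil-like, 13 in the B cell-like and 44 in the T or NK cell-like class. By limma voom they were 1 in the mononuclear phagocyte-like and 0 in the T or NK cell-like class (660 at an unadjusted p under 0.05). Without the filter on low counts they were 13, 1229, 230, 524 and 78 in the proximal tubule-like, thick ascending limb-like, distal convoluted tubule-like, intercalated cell-like and endothelial-like classes, 2, 107 and 33 in the mononuclear phagocyte-like, neutrophil-like and T or NK cell-like classes, and 26 lists passed in the proximal tubule-like class, against 7 with equal cell numbers.

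With the replicate number as a block for the pairing, 99 genes passed in the proximal tubule-like, 126 in the thick ascending limb-like, 2 in the distal convoluted tubule-like, 7 in the mesenchymal-like, 5 in the mononuclear phagocyte-like, 1 in the B cell-like and 53 in the T or NK cell-like class. The counts in the intercalated cell-like (92) and endothelial-like (20) classes stayed within 1.5 times. Lists in the whole-library sums that passed only with the block were glycolysis (-0.48), oxidative stress and NRF2 targets (-0.50) and the markers of principal (-0.62), mesenchymal (1.51), neutrophil (1.15) and T or NK (1.14) cells. In the intercalated cell-like class cytosolic ribosomal proteins passed only with it (0.15). Genes named in the text that crossed the threshold only with the block were Ccl8, Ccl9, Cxcl2, Ccl7, Cxcl1, Spp1 and Vim in the proximal tubule-like class, Apoe in the distal convoluted tubule-like, Lyz2 and Igfbp3 in the mesenchymal-like, Mmp13 in the mononuclear phagocyte-like and Cxcl2 in the B cell-like class. With it Klhdc8a, Mthfd2, Tg and Morn1 missed the threshold. The counts of lists past the test went with the block from 17 to 16 in the endothelial-like, 13 to 15 in the mononuclear phagocyte-like, 13 to 16 in the B cell-like and 11 to 13 in the T or NK cell-like class. The block changed no call of a share.

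At 1000 UMIs or more per cell the thick ascending limb-like count was 97, and with a mitochondrial share under 25% it was 707, with 194 in the intercalated cell-like class. With doublets kept the counts were 92 in the thick ascending limb-like, 1 in the mononuclear phagocyte-like and 23 in the T or NK cell-like class. With the class from each cell's own score they were 0 in the thick ascending limb-like (edgeR, 1412 at an unadjusted p under 0.05), 68 in the distal convoluted tubule-like, 122 in the endothelial-like and 0 in the T or NK cell-like class (651). At a cluster resolution of 0.5 it was 1 in the proximal tubule-like class.

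With a single UMI minimum the counts were 0 in the thick ascending limb-like (edgeR, 670 at an unadjusted p under 0.05), 69 in the intercalated cell-like and 0 in the T or NK cell-like class (506). With RAS3 and RAS4 both left out they were 10 in the whole-library sums, 17 in the thick ascending limb-like, 7 in the distal convoluted tubule-like, 57 in the intercalated cell-like, 29 in the endothelial-like, 31 in the mononuclear phagocyte-like and 2 in the T or NK cell-like class. The share ratios (log2) that then passed were -1.74 for thick ascending limb-like, 2.01 for mesenchymal-like, 1.21 for mononuclear phagocyte-like and 1.54 for neutrophil-like cells. With the library set as a term the counts were 1 in the proximal tubule-like, 619 in the thick ascending limb-like, 15 in the distal convoluted tubule-like, 224 in the intercalated cell-like and 34 in the endothelial-like class.

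In cells without a phagocyte marker UMI the counts were 0 in the thick ascending limb-like (edgeR, 725 at an unadjusted p under 0.05) and 6 in the intercalated cell-like class, and in as many random cells 1 in the proximal tubule-like, 45 in the thick ascending limb-like, 1 in the distal convoluted tubule-like and 2 in the intercalated cell-like class. In cluster 4 alone 14 thick ascending limb-like genes passed, and in cluster 6 alone 0 (edgeR, 440 at an unadjusted p under 0.05).

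Leaving out 1 library at a time gave 0 to 209 genes in the whole-library sums, 0 to 1 in the proximal tubule-like, 75 to 716 in the thick ascending limb-like, 0 to 83 in the distal convoluted tubule-like, 0 to 188 in the intercalated cell-like, 0 to 29 in the endothelial-like, 0 to 1 in the mesenchymal-like, 0 to 20 in the mononuclear phagocyte-like and 0 to 9 in the T or NK cell-like class. The largest counts came without RAS4 (whole-library sums, 209), sham2 (thick ascending limb-like, 716), RAS1 (distal convoluted tubule-like, 83, and intercalated cell-like, 188) and RAS3 (endothelial-like, 29, and mononuclear phagocyte-like, 20). The endothelial-like share ratio ran from -3.21 (without RAS1) to -1.40.

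Lists reversed under added settings as follows (median log2). In the intercalated cell-like class, cytosolic ribosomal proteins went to -0.15 without RAS3 and RAS4, mature proximal tubule transport to 0.81 in cells without a phagocyte marker UMI and 0.81 in random cells, mitochondrially encoded genes to 0.38 and 0.45 in these, and proximal tubule markers to 0.81 in the former. In the thick ascending limb-like class, cluster 4 alone gave mature proximal tubule transport at 0.84, oxidative stress and NRF2 targets at 0.11 and proximal tubule markers at 0.63. Cluster 6 alone gave mitochondrially encoded genes at -0.59, cytosolic ribosomal proteins at 0.17 and thick ascending limb markers at -0.35.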

Other observations

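The tests on unnamed clusters below were chosen only after the clusters were seen.

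Several clusters without a class name carried a clear program. Cluster 2, led by the cell division genes Top2a, Birc5 and Mki67, held 0.642% ± 0.094 of kept cells in sham and 1.85% ± 0.914 in RAS (SD, n = 4 each), above sham in 4 of 4 RAS libraries. Cluster 5, led by the hemoglobin genes Hbb-bs and Hba-a1 beside the proximal tubule gene Gatm, held 10.3% ± 3.02 and 2.54%, below sham in 4 of 4. The 2-sided exact permutation test gave p = 0.0286 for each, the smallest possible, and 0.172 after adjustment over the unnamed clusters, so neither passed.

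Clusters led by dendritic cell genes also stayed without a class name. Cluster 21 (Cd209a, Ccl17) held 0.681% ± 0.201 in sham and 5.24% ± 6.75 in RAS, with 15.1% in RAS4 and 0.085% in RAS3. Cluster 24 (Naaa, Xcr1, Clec9a), the genes of cross-presenting dendritic cells, held 0.665% ± 0.217 and 2.09% ± 1.78, and cluster 28 (Siglech), the gene of plasmacytoid cells, 0.483% ± 0.387 and 0.754% ± 0.511 (SD, n = 4 each; 2-sided exact permutation p = 0.143, 0.2 and 0.429). Cluster 17, with the urothelial Upk3a, the renin gene Ren1 and the contractile Tagln among its leading genes, held 0.781% ± 0.245 and 1.78% ± 1.14 (exact p = 0.0571). Clusters 8, 9, 13, 14, 19 and 25 came mostly from RAS3, which gave 82.5 to 93.4% of their cells.

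Lists in other classes also passed with the preset correlation. In mesenchymal-like cells MHC class II genes had a median log2 ratio of 2.67 (7 of 7 over the list alone), in T or NK cell-like cells 1.83 (7 of 7) and in neutrophil-like cells 1.07 (6 of 7). Complement genes had a median of 1.91 in T or NK cell-like (4 of 5), 1.61 in endothelial-like (6 of 9) and 1.25 in neutrophil-like cells (3 of 6). In B cell-like cells secreted factors of senescent cells had a median of 1.26 (4 of 11; adjusted p = 0.0471 with an estimated correlation, a call lost with the replicate block), beside markers of mononuclear phagocytes at 1.14 (4 of 11) and of T or NK cells at 1.48 (0 of 5). Cluster 0 held 89.4% of this class in sham and 70.1% in RAS. In neutrophil-like cells the phagocyte genes C1qb (1.52) and C1qa (1.33) stood higher and Cx3cr1 lower (-0.37), none past the threshold, and the phagocyte marker list did not pass (median 0.29 over 10 genes, camera adjusted p = 0.242). Tubule injury genes had a median of 0.78 in mononuclear phagocyte-like cells (9 of 16), and cholesterol synthesis stood at -0.40 in endothelial-like cells (2 of 17 lower over the list alone). No other list in this paragraph passed with an estimated correlation.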
